A study of Homo sapiens with 15 samples.

How the data were processed

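Messenger RNA was sequenced from NCI-H1975, an established human non-small cell lung cancer cell line whose growth depends on a mutated EGFR. The 15 libraries form 5 groups of 3: control, almonertinib (a small-molecule inhibitor of the EGFR kinase), EGF (the ligand of EGFR), siNC (a negative-control siRNA) and siEGFR (an siRNA against EGFR). Per the labels, RNA was extracted with TRIzol, enriched with oligo(dT) beads, made into paired-end libraries with an ABclonal kit and sequenced on an Illumina instrument. The labels give no dose, treatment time or culture condition, and they name the control group only as control. They do not say whether the replicates are separate cultures, so every p-value below measures only the spread between these libraries, which may be technical.

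The authors deposited FPKM values in a single table (fragments per kilobase of gene, scaled to the depth of the library) of 61248 loci and 15 libraries. Of these loci, 60605 carry an Ensembl gene ID and 643 are loci that the authors added. The submitters' processing notes name HISAT2, featureCounts, DESeq2 and the build hg19, without versions or roles. Gene symbols came from a separate list of gene names by Ensembl ID, which matched 60463 loci. Gene type, GC content and gene length came from GENCODE v29, and no genomic positions are given because that annotation is on another build. The deposited FPKM are unrounded, so the values of a gene are multiples of a step per read. From these steps the read total behind each library was recovered, and 99.995% of the positive values were whole within 0.01 reads. Totals ranged from 18009903 to 34908302 reads, so that 1 read in a gene of 1 kb equals 0.0286 to 0.0555 FPKM. The recovery was tested on simulated data.

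Genes with at least 1 FPKM in at least 3 of the 15 libraries were kept, which left 14999 loci, 488 of them added by the authors. The values log2(FPKM + 1) were fitted with limma 3.58.1 in R 4.3.3, with an intensity trend, robust variance moderation, 1 coefficient per group and no further scaling. The 15 libraries share 1 estimate of spread with 10 residual degrees of freedom. The added 1 shrinks fold changes of genes below a few FPKM, so the change of such a gene understates the ratio of its group means, and means are not given for each of them. The contrasts, tested two-sided, were almonertinib, EGF and siNC each against control, siEGFR against siNC, almonertinib against EGF, and the almonertinib and the EGF effect each minus the siEGFR effect. Benjamini-Hochberg adjusted p under 0.05 within a contrast was the threshold. In the text, rose, fell and changed refer to genes or lists past it.

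The comparisons, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule names EGFR, the 6 largest increases and the 6 largest decreases per comparison, and 3 list members with the smallest p. The largest changes needed a mean of at least 5 FPKM in the higher group, no overlap of replicates and a symbol that is not a clone or pseudogene. The 3 members come from the EGFR family list, the ERK list and up to 6 other lists with the smallest p. For the differences between treatments, the 4 largest in each direction are named, and for siNC against control at least the 3 largest. Some genes that the rule gives are not reported here, though they stayed in every test and count. Other list members given as examples were chosen after their values were seen. The 29 gene lists were tested with camera of limma at a preset correlation of 0.01 and again with a correlation estimated from the data, each with Benjamini-Hochberg adjustment over the lists.

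Effects were compared by Pearson and Spearman correlation across genes and by counting shared calls beside the number that independent lists give. Where effects share control libraries, the correlation that the sharing gives was simulated with 100 draws of independent genes and 100 draws in which genes varied together. Alternatives changed the pseudocount to 0.1, the filter, the scaling (TPM or median ratios), the libraries in the fit, the variance trend, the replicate number as a block and the threshold, or left out each library in turn. Added after seeing the data were limma-voom on the recovered reads, 1 weight per group, removal of GC and length trends with splines of 4 degrees of freedom for 14410 genes, and fits without control 1 and almonertinib 3. The limma step was tested on simulated data with 200 changed genes, where genes varied independently with the fitted spread and added counting noise. The camera step was tested with 1 raised list. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made the read totals and the figures, and version 1.17.8 of the R package data.table read the files. Nothing in the table was left out beyond the filter.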

Results

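Gene expression was measured in 15 libraries of the NCI-H1975 lung cancer line, 3 each from control cells, almonertinib, EGF, the negative-control siRNA (siNC) and the EGFR siRNA (siEGFR). Read totals in replicate order were 21100647, 19013968 and 18009903 for control and 20142786, 22205939 and 20145143 for almonertinib. They were 24568879, 23663624 and 31379222 for EGF, 19844536, 19979929 and 34908302 for siNC and 23813985, 22761132 and 20888335 for siEGFR. Between 27774 and 31109 genes had a value above 0 per library. Levels below are mean FPKM ± SD with n = 3 per group, and changes are log2 fold changes ± SE from limma with Benjamini-Hochberg adjusted p.

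The groups separated in their transcriptomes, and the siRNA groups lay closest together. The leading principal component held 69.2% of the variance and ran from almonertinib over control and EGF to siNC and siEGFR. The next held 12.9% and set EGF apart, and the one after it, with 6.08%, spread the replicates of control, almonertinib and EGF. The median SD within a group, in log2 units, was 0.137 for control, 0.136 for almonertinib, 0.101 for EGF, 0.050 for siNC and 0.039 for siEGFR. Control 1, almonertinib 3 and EGF 2 lay farthest from the other libraries of their groups on the component with 6.08%. MALAT1, a nuclear noncoding RNA, was at 99.4, 48.5 and 70.0 FPKM in control 1, 2 and 3. GAPDH, a glycolytic enzyme, was at 1075, 1563 and 1305 FPKM in these. In almonertinib 1, 2 and 3 MALAT1 was at 66.6, 55.1 and 86.0 FPKM.

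**Figure D1:**
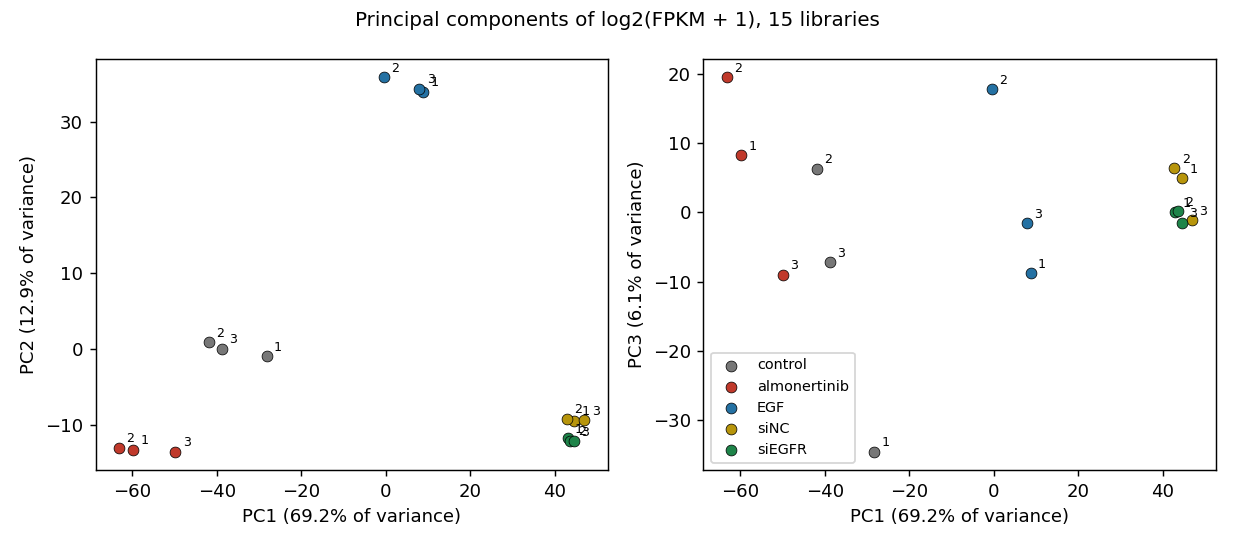
Principal components of log2(FPKM + 1) over the 14999 tested genes, with the axes giving the component scores and their share of the variance; each point is 1 of 15 libraries, coloured by group and marked with its replicate number. The 3 libraries of each group lie together on the first 2 components, and control 1 lies apart on the third.

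EGFR (ENSG00000146648), the receptor that the drug, the ligand and the siRNA act on, was at 49.6 ± 0.218 FPKM in siNC and 29.1 ± 0.666 FPKM in siEGFR (SD, n = 3). The knockdown thus left 58.8% of the transcript, a change of -0.75 ± 0.11 (adjusted p = 0.00165), and every siEGFR library lay below every siNC library. With almonertinib EGFR fell from 24.4 ± 3.17 to 16.7 ± 2.18 FPKM, which is 68.5% of control (-0.52 ± 0.11, adjusted p = 0.00521). In a fit of these 6 libraries alone the adjusted p was 0.0662, and over the 18 alternatives it ran from 0.000705 to 0.0662. With EGF it was at 25.4 ± 4.26 FPKM and did not pass (0.05 ± 0.11, adjusted p = 0.722). In siNC it was at 203.4% of control (1.00 ± 0.11, adjusted p = 4.9e-06).

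**Figure D2:**
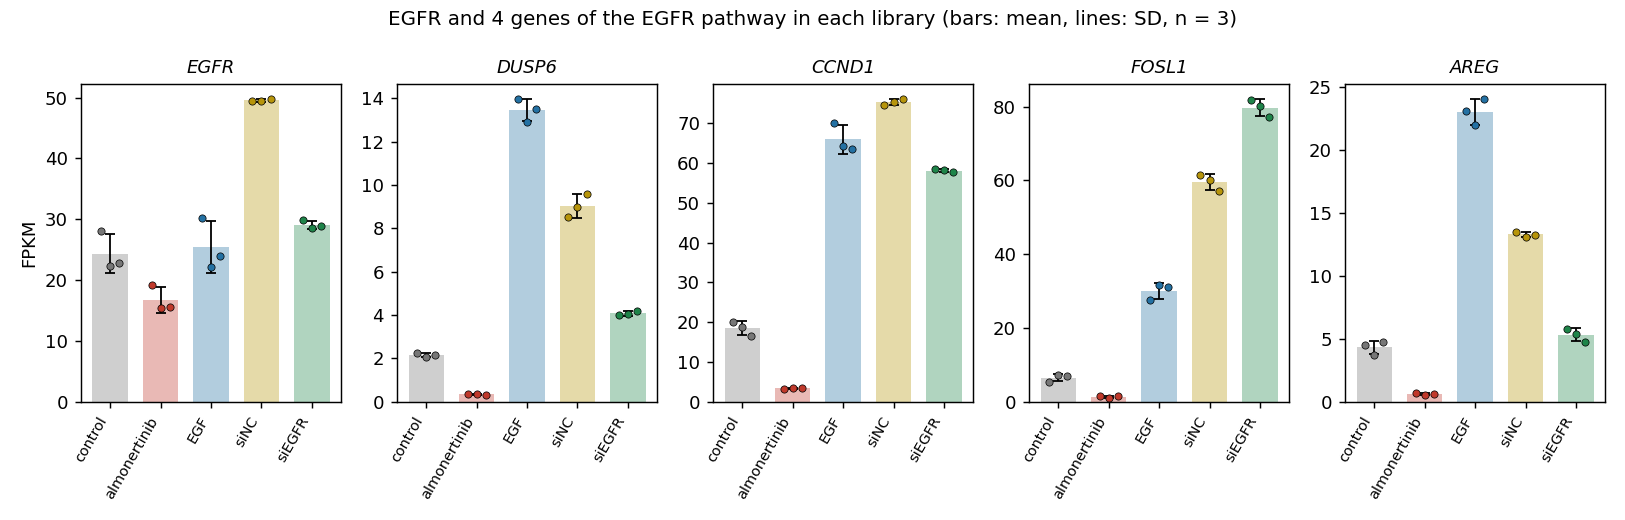
FPKM of EGFR, DUSP6, CCND1, FOSL1 and AREG in each library, with bars for the group mean and lines for the SD (n = 3), on axes that start at 0. DUSP6 is at 2.16 FPKM in control, 0.343 with almonertinib, 13.5 with EGF, 9.04 in siNC and 4.07 in siEGFR.

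Almonertinib against control shows the response to inhibition of the receptor. EGR1 (ENSG00000120738), an immediate early transcription factor, fell from 13.7 ± 1.24 to 0.37 ± 0.0655 FPKM (-3.42 ± 0.08, adjusted p = 4.09e-11). CCND1, which encodes cyclin D1, fell from 18.5 ± 1.71 to 3.37 ± 0.119 FPKM (-2.15 ± 0.06, adjusted p = 3.16e-10), and PHLDA2, an imprinted growth regulator, from 41.4 ± 2.79 to 7.44 ± 0.948 FPKM (-2.33 ± 0.08). The AP-1 subunit FOSL1 fell by 1.69, the transglutaminase TGM2 by 1.57 and the drug transporter ABCC3 by 1.46 on the log2 scale. In the other direction, ID2 rose from 6.33 ± 0.763 to 23.2 ± 1.13 FPKM (1.73 ± 0.08, adjusted p = 7.32e-08) and ID3 from 31.2 ± 2.91 to 82.8 ± 6.22 FPKM (1.38 ± 0.07). Both encode inhibitors of basic helix-loop-helix transcription factors. HSD17B14, a steroid dehydrogenase, rose from 5.35 ± 1.34 to 23.7 ± 2.17 FPKM (1.98 ± 0.12), and CSDC2, RENBP and ZNF114 rose by 1.49, 1.45 and 1.39.

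The ERK output list holds feedback phosphatases and other transcripts that ERK induces. With almonertinib 18 of its 19 tested members fell and IER3 did not pass (-0.26), with 18 also when adjusted over the list alone (camera adjusted p = 7.57e-15). DUSP6, an ERK phosphatase, fell from 2.16 ± 0.0821 to 0.343 ± 0.027 FPKM (-1.23 ± 0.05) and SPRY4, a feedback inhibitor, from 2.30 ± 0.175 to 0.419 ± 0.0638 FPKM (-1.22 ± 0.06). Of 8 receptors and ligands of the EGFR family, 6 fell (adjusted p = 0.000174, and adjusted p = 0.0562 with an estimated correlation). Among them the ligand AREG fell from 4.32 ± 0.543 to 0.616 ± 0.0605 FPKM (-1.71 ± 0.08), EREG from 3.31 ± 0.635 to 1.348 ± 0.103 FPKM (-0.87) and NRG1 from 2.0 ± 0.208 to 1.11 ± 0.0571 FPKM (-0.51). Of 17 immediate early genes, 9 fell and IER2 rose (adjusted p = 0.000872). Of 19 targets of YAP and TEAD, which report on adhesion and cytoskeletal tension, 13 fell and GADD45B rose (adjusted p = 6.79e-05), with CCN2 at -1.38. In a fit of the 6 libraries alone 12 ERK output, 4 EGFR family, 5 immediate early and 7 YAP and TEAD genes fell.

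Biosynthetic and cell cycle genes were lower with the drug. In the ribosome biogenesis list 17 of 24 members fell (adjusted p = 3.46e-07), with RRS1 at -0.97 ± 0.08, NOLC1 at -0.73 ± 0.07 and POLR1A, the large subunit of RNA polymerase I, at -0.62 ± 0.06. In cholesterol synthesis 16 of 23 fell and LSS rose (adjusted p = 1.69e-05). HMGCS1 fell from 17.3 ± 1.53 to 8.28 ± 1.2 FPKM (-0.98 ± 0.09) and INSIG1 by 0.56. In fatty acid synthesis 10 of 13 fell, 12 when adjusted over the list alone (adjusted p = 4.34e-05). There the desaturase SCD fell from 103 ± 3.79 to 68.9 ± 4.14 FPKM (-0.57 ± 0.05), FADS1 by 0.67 and ACLY by 0.64, while the regulator SREBF1 rose by 0.50. In the G1/S list 12 of 30 fell, 14 when adjusted over the list alone, and CDT1 rose by 0.93 (adjusted p = 0.00052). In the mitotic list 15 of 29 fell, 17 when adjusted over the list alone (adjusted p = 2.28e-05, and adjusted p = 0.28 with an estimated correlation). KIF20A fell by 0.41, BUB1B from 3.66 ± 0.541 to 2.03 ± 0.325 FPKM (-0.62) and KIF23 from 3.02 ± 0.1 to 2.06 ± 0.267 FPKM (-0.40), and KIF23 had an adjusted p of 0.0684 in the fit of the 6 libraries, the highest of 18 alternatives from 0.000309. Mitotic genes had a median loading of 0.938 on the axis along which control 1 and almonertinib 3 stood apart, against 0.24 for protein-coding genes, and without these libraries 19 fell. In the fit of the 6 libraries 8 ribosome biogenesis, 9 cholesterol, 5 fatty acid, 3 G1/S and 4 mitotic genes fell, so these counts depend on the libraries that share the estimate of spread.

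Lysosomal, stress and antigen presentation genes were higher with the drug. In the lysosome and autophagy list 11 of 25 members rose and 0 fell (adjusted p = 1.69e-05). The autophagy receptor SQSTM1 rose from 61.0 ± 1.74 to 84.0 ± 3.89 FPKM (0.45 ± 0.04), ATG9B by 0.73 and GABARAPL1 by 0.43. Of 22 ATF4 targets of the amino acid response, 10 rose and 2 fell, 5 when adjusted over the list alone (adjusted p = 0.00402), led by NUPR1 at 1.22 and SLC7A5, an amino acid transporter, at 0.92, while PSAT1 fell by 0.68. Of 16 antigen presentation genes, 8 rose and 2 fell (adjusted p = 0.00633), with HLA-F at 0.57 (HLA genes share sequence, so their reads are not certain to be their own). In the list of replication-dependent histones 4 of 8 genes rose (adjusted p = 0.00278). The oligo(dT) beads enrich polyadenylated RNA, so these values may not cover all histone transcripts. Of 24 FOXO targets 8 rose and 3 fell (adjusted p = 0.0104, and adjusted p = 0.223 with an estimated correlation). Of 28 ribosomal protein genes, 11 rose, 20 when adjusted over the list alone (adjusted p = 5.28e-07, and adjusted p = 0.223 with an estimated correlation). RPS19 rose by 0.35 and RPL18 by 0.34, but 0 of the 28 passed in the fit of the 6 libraries, where these 2 had adjusted p = 0.0711 and 0.117, and 3 rose without control 1 and almonertinib 3. The lowest adjusted p over the 18 alternatives were 0.00364 and 0.00571. Of 4 tested fibroblast markers COL1A1 rose by 0.51, and 3 when adjusted over the list alone (adjusted p = 0.0104, and adjusted p = 0.249 with an estimated correlation). In the fit of the 6 libraries 4 lysosome genes rose, 5 ATF4 targets rose and 1 fell, 1 antigen presentation gene rose and 1 fell, 5 FOXO targets rose and 0 of 8 histone genes passed. As lists, the 16 past the threshold also passed in that fit, with adjusted p up to 0.0174. The BCL2 family, glycolysis, ER chaperone, interferon, NF-kB, p53, mesenchymal, epithelial, alveolar, TGF-beta, hypoxia, leukocyte and mitochondrial lists did not pass.

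With almonertinib 1817 genes rose and 2700 fell, of which 29 and 57 changed at least 2-fold, and the replicates of 35.2% of tested genes did not overlap, against 10% by chance. Of the 16 lists past the threshold, 7 higher and 9 lower, 4 higher and 7 lower ones held with an estimated correlation. A fit of the 6 libraries alone gave 399 higher and 458 lower genes, the decreases numbered 1623 without almonertinib 2 and 1779 without control 1, and 4517 calls became 3940 without control 1 and almonertinib 3. In the simulation, which added counting noise to the fitted spread, 104 of 261 calls were unchanged genes with all 15 libraries and 7 of 98 with the 6 libraries. The 104 were 0.703% of the unchanged genes. Few genes were changed there and genes varied independently, so the share of unchanged genes does not carry over to the 4517 real calls. The simulated fits of 15 and of 6 libraries recovered 61.2% and 9% of the genes changed 1.5-fold, so single genes with small changes are uncertain. The share of calls that were higher, 40.2%, was 23.6% after TPM scaling and 50.4% after median-ratio scaling.

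EGF against control shows the response to the ligand. The secreted factor ANGPTL4 (ENSG00000167772) rose from 2.99 ± 0.378 to 25.1 ± 1.66 FPKM (2.72 ± 0.08, adjusted p = 8.25e-11, n = 3). The collagenase MMP1 rose from 1.12 ± 0.119 to 10.7 ± 0.436 FPKM (2.46 ± 0.07), PTX3, a soluble pattern recognition protein, from 6.57 ± 0.857 to 39.9 ± 1.94 FPKM (2.44 ± 0.09), and HMGCS1, an enzyme of cholesterol synthesis, from 17.3 ± 1.53 to 92.0 ± 4.63 FPKM (2.35 ± 0.09). TMEM158 and FGFBP1, which releases fibroblast growth factors from the matrix, rose by 2.44 and 2.31. CCN5 fell from 51.8 ± 9.41 to 8.16 ± 0.796 FPKM (-2.52 ± 0.12, adjusted p = 5.65e-09), and MLXIPL, a glucose-responsive transcription factor, from 11.8 ± 1.06 to 1.27 ± 0.118 FPKM (-2.50 ± 0.10). The metallothionein MT1E fell by 2.46, CSDC2 by 2.38, the polarity gene LLGL2 by 2.33 and SPINK4 by 2.33. MT1E has near-identical relatives, so its reads are not certain to be its own.

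In the ERK output list 18 of 19 members rose with EGF and SPRY1 fell by 0.21 (adjusted p = 1.19e-11). DUSP6 rose from 2.16 ± 0.0821 to 13.5 ± 0.522 FPKM (2.19 ± 0.05), CCND1 from 18.5 ± 1.71 to 66.0 ± 3.66 FPKM (1.78 ± 0.06) and SPRY4 by 1.59. Of 17 immediate early genes 14 rose (adjusted p = 8.03e-07). In the EGFR family 5 of 8 rose and ERBB2 fell by 0.56 (adjusted p = 0.0116, and adjusted p = 0.174 with an estimated correlation). AREG rose to 23.1 ± 1.02 FPKM (2.18 ± 0.08), and the ligands NRG1 and HBEGF rose from 2.0 ± 0.208 to 4.81 ± 0.406 FPKM (0.95) and from 2.51 ± 0.0465 to 5.67 ± 0.162 FPKM (0.93). All 30 members of the G1/S list rose (adjusted p = 8.43e-20), among them RRM2, a subunit of ribonucleotide reductase, from 1.86 ± 0.0438 to 9.17 ± 0.548 FPKM (1.83), the replication licensing factor CDC6 from 1.39 ± 0.0768 to 6.57 ± 0.465 FPKM (1.66) and MCM4 by 1.07. All 29 mitotic genes rose (adjusted p = 8.43e-20), with KIF20A at 1.15, UBE2C at 1.55 and the kinase AURKA at 1.63.

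Metabolic genes also rose with EGF. In cholesterol synthesis 20 of 23 rose, 21 when adjusted over the list alone, and TM7SF2 fell (adjusted p = 3.83e-14), with INSIG1 from 23.6 ± 1.31 to 87.9 ± 5.79 FPKM (1.85 ± 0.06) and FDPS from 29.9 ± 0.845 to 93.5 ± 6.35 FPKM (1.61 ± 0.06). In glycolysis 20 of 21 rose and PFKM fell (adjusted p = 2.73e-11). PGK1 rose from 103 ± 4.14 to 312 ± 9.26 FPKM (1.59 ± 0.06), LDHA from 191 ± 10.7 to 534 ± 19.7 FPKM (1.48 ± 0.08) and PGAM1 by 1.20. Of 18 HIF1 targets 15 rose, 16 when adjusted over the list alone (adjusted p = 2.08e-09), with the growth arrest gene NDRG1 at 1.85 and the carbonic anhydrase CA9 at 2.29 beside ANGPTL4. In ribosome biogenesis 23 of 24 rose and NOB1 fell (adjusted p = 2.66e-10), with DKC1 at 0.74, NOLC1 at 0.87 and RRP12 at 0.82. In fatty acid synthesis 10 of 13 rose and 1 fell (adjusted p = 4.04e-06), and of 22 ATF4 targets 14 rose and 2 fell (adjusted p = 0.000167). Of 16 ER chaperones 9 rose (adjusted p = 0.0191, and adjusted p = 0.323 with an estimated correlation).

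Fewer lists were lower with EGF. Of 24 FOXO targets 19 fell, 20 when adjusted over the list alone (adjusted p = 9.29e-06), with the ubiquitin ligase FBXO32 at -1.47 and PIK3IP1, a negative regulator of PI3 kinase, at -1.27. Of 19 epithelial genes 11 fell (adjusted p = 0.00414, and adjusted p = 0.0814 with an estimated correlation), with E-cadherin (CDH1) at -1.09. The 4 fibroblast markers fell (adjusted p = 0.000896, and adjusted p = 0.114 with an estimated correlation), and 6 of 8 histone genes fell and 1 rose (adjusted p = 0.0351, and adjusted p = 0.113 with an estimated correlation). In total 3306 genes rose and 4090 fell, 366 and 339 of them at least 2-fold, and 51.1% of genes showed no overlap of replicates against 10% by chance. Of 12 higher and 4 lower lists, 10 and 1 held with an estimated correlation. The share of calls that were higher was 44.7%, and 57.7% after median-ratio scaling.

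**Figure D3:**
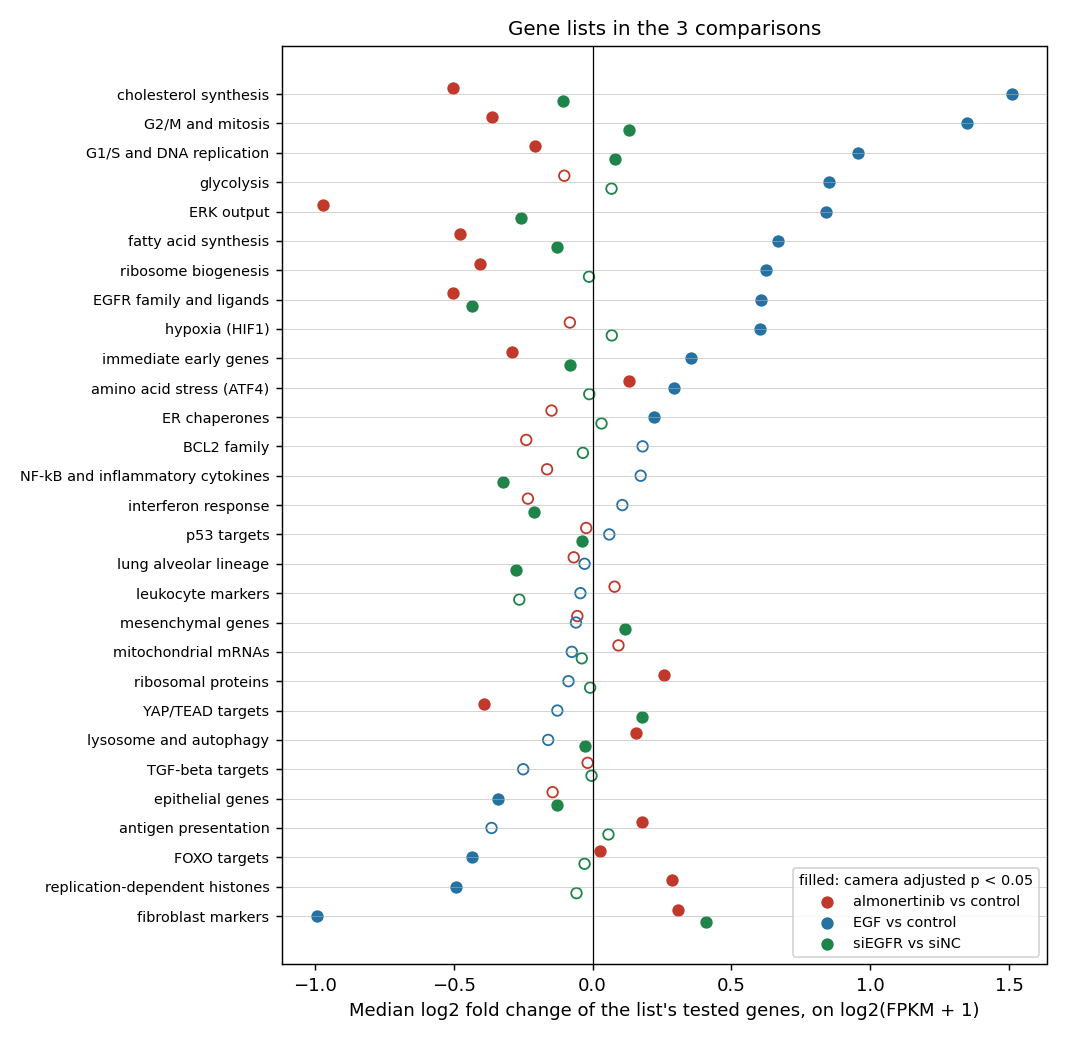
Median log2 fold change of the tested members of each of 29 gene lists in 3 comparisons, with a filled point where the camera adjusted p was under 0.05 at the preset correlation. The ERK output list is at -0.97 with almonertinib, 0.84 with EGF and -0.26 with the EGFR siRNA.

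The siRNA against EGFR was compared with the negative-control siRNA. No other group received an siRNA against EGFR, so changes against siNC are not shown to follow from the lower EGFR transcript. SFTPA1 (ENSG00000122852), a surfactant protein of alveolar type II cells, fell from 5.83 ± 0.397 FPKM in siNC to 0.18 ± 0.0524 FPKM in siEGFR (-2.53 ± 0.07, adjusted p = 5.6e-10, n = 3). AREG fell from 13.3 ± 0.198 to 5.33 ± 0.516 FPKM (-1.18 ± 0.08, adjusted p = 1.58e-06). The protease inhibitor TFPI2 fell from 51.3 ± 3.14 to 24.3 ± 0.0913 FPKM (-1.05 ± 0.14), SERPINB4 by 1.16, TCIM by 1.14 and C11orf86 by 1.07. Among the largest increases, MYL9, a myosin light chain, rose from 39.2 ± 1.06 to 70.7 ± 0.508 FPKM (0.83 ± 0.06), TAGLN from 5.74 ± 0.0924 to 10.4 ± 0.292 FPKM (0.76 ± 0.05) and ACTA2 from 8.72 ± 0.907 to 15.4 ± 0.657 FPKM (0.76 ± 0.10). P3H3, a collagen prolyl hydroxylase, rose by 0.96, the TNF family ligand CD70 by 0.85 and PSG4 by 0.77. SFTPA1, SERPINB4 and PSG4 have near-identical relatives, so their reads are not certain to be their own.

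In the ERK output list 8 of 19 members fell after knockdown, 10 when adjusted over the list alone, and FOSL1 rose by 0.41 (adjusted p = 1.25e-08). DUSP6 fell from 9.04 ± 0.547 to 4.07 ± 0.1 FPKM (-0.98 ± 0.05), SPRY4 by 0.51 and the phosphatase DUSP4 by 0.41. In the EGFR family 4 of 8 fell (adjusted p = 4.38e-05, and adjusted p = 0.0508 with an estimated correlation), which were EGFR, AREG, EREG and TGFA, the last from 8.38 ± 0.207 to 4.0 ± 0.25 FPKM (-0.91 ± 0.06). EGFR is itself the target of the siRNA, and the list was not tested without it. Of 17 immediate early genes 4 fell, 6 when adjusted over the list alone (adjusted p = 0.000696), with KLF4 at -0.48, EGR1 at -0.49 and JUNB at -0.32. JUNB had an adjusted p of 0.0556 after median-ratio scaling, and 4.46e-05 to 0.0556 over 17 alternatives. In a fit of the 6 siRNA libraries alone 11 ERK output, 5 EGFR family and 6 immediate early genes fell, and 1 ERK output and 1 immediate early gene rose.

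Inflammatory, interferon and alveolar genes fell. Of 18 NF-kB targets and cytokines 6 fell, 14 when adjusted over the list alone (adjusted p = 3.62e-12). The adhesion molecule ICAM1 fell from 21.8 ± 0.754 to 13.2 ± 0.365 FPKM (-0.68 ± 0.07), and TNFAIP3 and NFKBIA, inhibitors of NF-kB, by 0.70 and 0.45. Of 28 interferon response genes 7 fell, 10 when adjusted over the list alone (adjusted p = 1.65e-08), with the oligoadenylate synthetases OAS1 at -0.68 and OAS3 at -0.55 and the related OASL at -0.36. Of 13 alveolar lineage genes 6 fell, 8 when adjusted over the list alone (adjusted p = 7.87e-10), with SFTPB from 3.40 ± 0.111 to 0.726 ± 0.0553 FPKM (-1.35 ± 0.09) and LAMP3 from 2.51 ± 0.0793 to 0.31 ± 0.0743 FPKM (-1.42 ± 0.07). Of 23 cholesterol synthesis genes 1 fell, 2 when adjusted over the list alone (adjusted p = 0.000696), and of 19 p53 targets 2 fell (adjusted p = 0.00415). Of 19 epithelial genes 2 fell, CDH1 by 0.62 and EPCAM by 0.78 (adjusted p = 0.000696, and adjusted p = 0.0508 with an estimated correlation). The fatty acid list, with 3 of 13 lower (adjusted p = 0.0198, and adjusted p = 0.113 with an estimated correlation), and the lysosome list, with 4 of 25 lower (adjusted p = 0.0468, and adjusted p = 0.113 with an estimated correlation), did not pass after median-ratio scaling. In the fit of the 6 siRNA libraries 13 NF-kB, 16 interferon, 9 alveolar, 9 cholesterol, 4 p53, 9 epithelial, 7 fatty acid and 9 lysosome genes fell. In that fit 1 interferon, 1 alveolar, 2 epithelial, 2 fatty acid and 4 lysosome genes rose, and the lysosome list did not pass (adjusted p = 0.0576).

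In siEGFR 5 lists were higher at the preset correlation, and 0 with an estimated one. Of 4 tested fibroblast markers 3 rose (adjusted p = 2.45e-05, and adjusted p = 0.0591 with an estimated correlation). COL1A2, a fibrillar collagen that every group of this line expresses, rose from 131 ± 3.87 to 178 ± 1.14 FPKM (0.44 ± 0.05), COL1A1 by 0.68 and PDGFRB by 0.37, and PDGFRB missed the threshold in 8 of 17 alternatives (adjusted p from 0.000235 to 0.173). Among 4 tested genes of the leukocyte list CD79A and CORO1A rose and CD14 and HBB, a globin gene, fell. That list did not pass (adjusted p = 0.582). Of 17 mesenchymal genes 4 rose and 2 fell, 7 rising when adjusted over the list alone (adjusted p = 0.00116, and adjusted p = 0.0638 with an estimated correlation). Of 19 YAP and TEAD targets CCN1, AJUBA, AXL and F3 rose and NT5E fell, 8 rising when adjusted over the list alone (adjusted p = 0.00466, and adjusted p = 0.0638 with an estimated correlation). In the mitotic list 2 of 29 rose, 5 when adjusted over the list alone (adjusted p = 0.000144, and adjusted p = 0.33 with an estimated correlation). These were KIF20A at 0.32 and CDC20 at 0.30, while ANLN was at 0.55 with an adjusted p of 0.0602. CDC20 missed the threshold in 6 of 17 alternatives (adjusted p from 8.92e-05 to 0.179), and ANLN ran from 0.000434 to 0.193. The G1/S list was higher with 0 of 30 members past the threshold (adjusted p = 0.0181, and adjusted p = 0.107 with an estimated correlation). In the fit of the 6 siRNA libraries 3 fibroblast, 9 mesenchymal, 10 YAP and TEAD, 15 mitotic and 4 G1/S genes rose, and 2 mesenchymal and 3 YAP and TEAD genes fell.

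After knockdown 340 genes rose and 479 fell, 6 and 24 of them at least 2-fold, and 40.5% of genes showed no overlap of replicates against 10% by chance. Of 5 higher and 11 lower lists, 0 and 7 held with an estimated correlation. A fit of these 6 libraries alone, which vary less than the others, gave 1617 higher and 1463 lower genes. Between replicates, the chi-square of the recovered reads per degree of freedom is 1 where only counting noise is present. It was 1.51 to 2.40 for siEGFR and 3.04 to 3.95 for siNC, against 6.60 to 39.2 for the other groups. The siRNA replicates thus lay closer to counting noise, so the spread behind the siEGFR calls may be largely technical. Leaving out any 1 of the 6 from the fit of 15 gave 152 to 180 higher and 287 to 349 lower genes. In the simulation, which added counting noise to the fitted spread, the fit of 15 libraries recovered 64.2% of genes changed 1.5-fold and called 0 unchanged genes. The fit of 6 libraries recovered 83.6% and called 17 unchanged genes. Genes varied independently there, so these counts do not give the number of false calls among the real ones.

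The siNC and control groups were compared as the background of the knockdown. FABP4, a fatty acid carrier, was at 121 ± 2.91 FPKM in siNC and 1.24 ± 1.11 FPKM in control (5.90 ± 0.25, adjusted p = 5.13e-10, n = 3). The neuroendocrine peptide precursor VGF rose from 6.18 ± 1.84 to 215 ± 7.81 FPKM (4.94 ± 0.14) and CBLC, an E3 ubiquitin ligase, from 0.381 ± 0.153 to 14.5 ± 0.493 FPKM (3.50 ± 0.08). The MHC class II gene HLA-DRA and CD74, which encodes the invariant chain of class II molecules, fell from 39.8 ± 0.768 to 1.67 ± 0.0989 FPKM (-3.93 ± 0.11) and from 72.7 ± 3.09 to 6.0 ± 0.57 FPKM (-3.40 ± 0.07). RRAD, a small GTPase, fell from 176 ± 37 to 13.1 ± 0.654 FPKM (-3.63 ± 0.17). All 30 G1/S genes (adjusted p = 1.7e-16) and all 29 mitotic genes rose (adjusted p = 5.26e-15, and adjusted p = 0.0863 with an estimated correlation). Of 19 ERK output genes 13 rose and 2 fell (adjusted p = 0.00139, and adjusted p = 0.0863 with an estimated correlation), with CCND1 at 1.97 and DUSP6 at 1.67. Of 16 antigen presentation genes 13 fell and 3 rose (adjusted p = 3.98e-05), with HLA-B at -3.01. In all 5159 genes rose and 4740 fell, 1089 and 790 of them at least 2-fold, and 68.8% of genes showed no overlap of replicates against 10% by chance. Of 10 higher and 6 lower lists, 3 and 2 held with an estimated correlation. Each treatment effect is given against its own control.

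Almonertinib and EGF were also compared directly, which removes the shared control libraries. The transmembrane glycoprotein GPNMB was at 42.3 ± 3.08 FPKM with almonertinib and 2.66 ± 0.303 FPKM with EGF (3.56 ± 0.07, adjusted p = 9.19e-13, n = 3). CSDC2, CCN5 and IGFL2-AS1 were higher by 3.87, 3.28 and 3.31, the last an antisense gene whose strand the labels do not settle. PHLDA2 was at 7.44 ± 0.948 FPKM with almonertinib and 174 ± 13.8 FPKM with EGF (-4.38 ± 0.08), and ANGPTL4, CCND1 and FGFBP1 were at -4.02, -3.94 and -3.92. With almonertinib 18 of 19 ERK output genes (adjusted p = 6.73e-12), 29 of 30 G1/S genes (adjusted p = 1.06e-13) and 20 of 23 cholesterol synthesis genes (adjusted p = 4.49e-10) were lower, and 20 of 24 FOXO targets were higher (adjusted p = 1.28e-05). The 29 mitotic genes were lower too (adjusted p = 1.25e-14, and adjusted p = 0.057 with an estimated correlation). In all 4500 genes were higher with almonertinib and 4893 lower, and 61.7% of genes showed no overlap against 10% by chance. Across genes the effects of almonertinib and EGF against control correlated with r = -0.36 (Spearman rho = -0.33), and with r = -0.2255 without control 2. Sharing the control libraries alone would give r = 0.50 with independent genes and r = 0.46 where genes vary together. Genes are not independent replicates. Of 2921 genes called in both, 1203 rose with the drug and fell with EGF and 1189 did the reverse, where independent lists give 495 and 595.

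The drug and the knockdown, each against its own control, were compared by testing the difference of the effects. ERK output fell further with almonertinib than with the siRNA: 12 of 19 genes were lower in the difference, 13 when adjusted over the list alone (adjusted p = 1.07e-08). The siRNA left 58.8% of the EGFR transcript, and siNC held 203.4% of that of control. The difference thus does not compare the drug with loss of EGFR. DUSP6 and FOSL1 were also higher in siNC than in control, so the added 1 shrinks changes unequally in the drug and siRNA arms. The largest negative differences were EGR1 at -2.93 ± 0.11 (adjusted p = 2.1e-08), FOSL1 at -2.11 ± 0.15, PHLDA2 at -1.90 ± 0.12 and CCND1 at -1.78 ± 0.09. The largest positive ones were SFTPA1 at 2.54 ± 0.10 (adjusted p = 2.1e-08), HSD17B14 at 2.38 ± 0.17, ID2 at 1.82 ± 0.12 and GPNMB at 1.72 ± 0.10. SFTPA1 was at 0.0433 ± 0.0565 FPKM in control and 0.0509 ± 0.0369 FPKM with almonertinib, so its difference only restates the decrease with the siRNA. In the difference, 10 of 19 YAP and TEAD targets (adjusted p = 3.59e-07) and 10 of 24 ribosome biogenesis genes (adjusted p = 1.14e-06) were lower, while 8 of 25 lysosome genes (adjusted p = 1.02e-06) and 4 of 18 NF-kB genes (adjusted p = 0.00209) were higher, with 1 lower in each. Of 29 mitotic genes 14 were lower (adjusted p = 2.14e-08, and adjusted p = 0.136 with an estimated correlation). In all 892 genes were higher and 1157 lower in the difference, and of 8 higher and 8 lower lists 4 and 5 held with an estimated correlation. The lower count was 1819 without almonertinib 3, 1744 without control 2, 733 and 753 without siNC 1 and siNC 2, and 766 and 731 without siEGFR 1 and siEGFR 3. The share of higher calls, 43.5%, was 27.2% after TPM scaling and 56.3% after median-ratio scaling.

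Across genes the drug and knockdown effects correlated with r = 0.10 (Spearman rho = 0.11), and genes are not independent replicates. It was 0.0476 without almonertinib 3, 0.0625 without control 2 and 0.0447 without siNC 3, and 0.085 to 0.1469 without any other of the 12 libraries. Among 379 genes called in both, 90 rose in both and 177 fell in both, where independent lists give 41.2 and 86.2. Another 47 rose with the drug and fell with the siRNA and 65 did the reverse, where independent lists give 58.0 and 61.2. The 267 genes that moved the same way became 143, 153 and 147 without siNC 1, 2 and 3 and 164, 138 and 143 without siEGFR 1, 2 and 3. The 112 that moved opposite ways became 53, 56 and 70 and 65, 58 and 52 without these, 73 without control 3 and 170 without almonertinib 3. The share that moved the same way was 64.3% to 74.7% over 23 alternatives. The shared decreases included EGFR, itself the target of the siRNA, and AREG, EREG, TGFA, DUSP6, SPRY4 and CCND1, while FOSL1, F3 and AXL fell with the drug and rose with the siRNA.

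**Figure D4:**
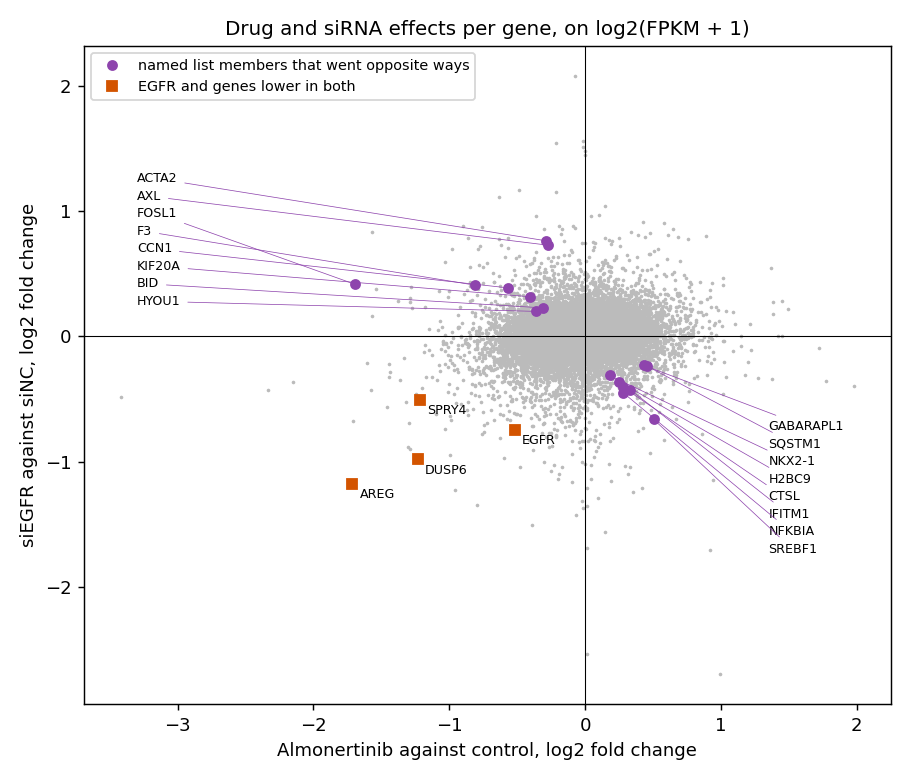
Log2 fold change of each tested gene with almonertinib against control (horizontal axis) and with siEGFR against siNC (vertical axis); squares are EGFR and 3 genes lower in both, and circles are 16 named list members that went opposite ways. AREG lies at -1.71 and -1.18, and FOSL1 at -1.69 and 0.41.

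The EGF and knockdown effects were compared in the same way. ANGPTL4 was higher in the difference by 3.60 ± 0.11 (adjusted p = 4.73e-10), SERPINB4 by 3.46 ± 0.18, AREG by 3.36 ± 0.11 and DUSP6 by 3.18 ± 0.08, and CCN5, CSDC2, TMEM86A and MT1E were lower at -2.68, -2.60, -2.49 and -2.45. CSDC2 and TMEM86A were at 0.52 ± 0.0827 and 1.32 ± 0.106 FPKM in siNC and at 0.777 ± 0.204 and 1.74 ± 0.0813 FPKM in siEGFR. In the difference 17 of 19 ERK output genes (adjusted p = 3.11e-14) and all 30 G1/S genes (adjusted p = 3.56e-18) were higher. In all 2556 genes were higher and 3196 lower, and of 15 higher and 3 lower lists 11 and 0 held with an estimated correlation. The share of higher calls was 44.4%, and 60.4% after median-ratio scaling, which moved the median of all genes from -0.04 to 0.06. Across genes the effects correlated with r = -0.07 (Spearman rho = -0.04), and r = -0.0444 without control 1. Of 558 genes called in both, 192 rose with EGF and fell with the siRNA and 155 did the reverse, where independent lists give 106 and 92.7. Genes that moved opposite ways numbered 191, 202 and 190 without siNC 1, 2 and 3 and 220, 193 and 189 without siEGFR 1, 2 and 3.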

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

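In this part the removal of GC content and length trends is the setting chosen only after the data were seen. Each gene here changed in opposite directions with almonertinib and with the EGFR siRNA, with 3 libraries per group. The difference of the effects also passed the limma test. Effects called with opposite signs add up in the difference, so this pass removed no gene and adds no support.

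Of the ERK output genes, FOSL1, an AP-1 subunit, had a difference (almonertinib effect minus siEGFR effect, log2) of -2.11, with -1.69 for the drug and 0.41 for the siRNA. The tissue factor gene F3 had a difference of -1.22 (-0.81 and 0.41). The smooth muscle actin ACTA2, which was near the floor in the drug arm (1.15 ± 0.184 FPKM in control and 0.76 ± 0.14 FPKM with almonertinib), was at -1.05 (-0.29 and 0.76). The receptor kinase AXL was at -0.996 (-0.27 and 0.73) and CCN1, a matrix protein and YAP target, at -0.95 (-0.57 and 0.39). The mitotic kinesin KIF20A was at -0.72, the ER chaperone HYOU1 at -0.56 and the BCL2 family member BID at -0.54. In the other direction, SREBF1, which encodes a regulator of lipid synthesis, had a difference of 1.17 (0.50 and -0.66). The interferon-induced IFITM1 was at 0.76, the NF-kB inhibitor NFKBIA at 0.73, the autophagy receptor SQSTM1 at 0.69, the protease CTSL at 0.68, GABARAPL1 at 0.67, the histone gene H2BC9 at 0.62 and the lung transcription factor NKX2-1 at 0.49. After the removal of GC content and length trends the NKX2-1 difference had an adjusted p of 0.154, the highest of its 24 alternatives, which began at 0.000555.

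In all, 112 genes went opposite ways in both comparisons, 65 lower with the drug and higher with the siRNA and 47 the reverse. The 112 became 53, 56 and 70 without siNC 1, 2 and 3, 65, 58 and 52 without siEGFR 1, 2 and 3, 73 without control 3 and 170 without almonertinib 3. Without a filter the count was 63, and with the replicate number as a block it was 159. The tables argue against a bias from GC content or gene length as the whole cause, since 81 of the 110 genes with a known GC content still went opposite ways past the threshold in both after its removal. This is weak evidence, because that setting called more genes: 1696 instead of 819 with siEGFR, and 306 that went opposite ways. Independent lists stay open for the number of such genes, which was 0.94 times the 119.2 that independent lists give, while the 267 genes that went the same way outnumber the 127.4 of independent lists. A difference between blocking the kinase and lowering the transcript to 58.8% may act on single genes. The drug and siRNA groups also differ in their baselines, and no test here separates these. Nor do these samples show that the siRNA changes follow from the lower EGFR transcript.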

How the results depend on the processing

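Tests chosen only after the data were seen are those with 1 weight per group, limma-voom, removal of GC content and length trends, only siNC 1 and 2, and without control 1 and almonertinib 3. No called named gene, list past the threshold or correlation changed direction in the alternatives run. Among all genes called in both, 6 of 8388 for siNC and 6 of 7598 for almonertinib against EGF changed direction after removal of GC content and length trends. Of 178 named genes and differences, 169 kept their call in every alternative run, and RPS19, RPL18, KIF23, EGFR, PDGFRB, CDC20, ANLN, JUNB and NKX2-1 did not. The rule picks large changes and small p in these same data, so this steadiness does not extend to other calls. The fit of only the groups compared kept 18.9% of the 4517 almonertinib calls. Leaving out 1 library of the siRNA groups kept 53% to 60.9% of the 819 siEGFR calls. Counts of genes stayed within 1.5 times in 230 cases and moved in 58. Single lists were followed only for almonertinib, EGF and siNC against control and siEGFR against siNC. They kept their call in 1428 cases, lost it in 52 (30 of them with an estimated correlation) and gained it in 24. Counts of genes called in both of 2 comparisons were the least steady, within 1.5 times in 80 cases and moved in 52. DESeq2 and edgeR, planned in case whole reads could be recovered, were not run although they were, and limma-voom on these reads took their place. It gave 4628 calls for almonertinib and 860 for siEGFR.

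A mean of at least 5 FPKM, which tests fewer genes, gave 1105 higher and 1649 lower for almonertinib, 1708 lower for EGF, and 178 and 256 for siEGFR. It gave 2857 and 2170 for siNC, 2085 and 2927 for almonertinib against EGF, 539 higher for drug minus siRNA and 1402 lower for EGF minus siRNA. Requiring a change of at least 1 in log2, which can only remove genes, left 29 higher and 57 lower for almonertinib, 366 and 339 for EGF, and 6 and 24 for siEGFR. It left 1089 and 790 for siNC, 759 and 841 for almonertinib against EGF, 55 and 51 for drug minus siRNA and 447 and 440 for EGF minus siRNA. The fit of only the groups compared gave 399 and 458 for almonertinib and 1617 and 1463 for siEGFR, and 1 weight per group gave 805 and 1307, and 1878 and 1665. The first uses only the spread of its own groups, with a median SD of 0.137 and 0.136 for control and almonertinib and of 0.050 and 0.039 for siNC and siEGFR. The second gives siNC and siEGFR weights of 2.16 and 2.37, and control and almonertinib 0.465 and 0.490.

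The cause was not tested for the other shifts. TPM scaling gave 1166 higher for almonertinib and 1736 lower for drug minus siRNA, and removal of GC content and length trends gave 809 and 887 for siEGFR and 2031 lower for drug minus siRNA. The replicate number as a block gave 1850 lower for drug minus siRNA, but the numbers do not pair the samples as a whole. Of 30 pairs with the same number 10 had r above 0.1, with r from -0.169 to 0.597. For 6 of 15 libraries the best partner had their own number. Replicate 2 did vary together in control, almonertinib, EGF and siNC, with r from 0.173 to 0.597. The correlation of EGF and siEGFR effects was -0.13 with limma-voom. Over 23 alternatives genes called with both almonertinib and siEGFR numbered 138 to 567 in the same direction and 52 to 306 in opposite ones. With EGF and siEGFR they numbered 102 to 824 and 189 to 1119, also over 23 alternatives. With almonertinib and EGF they numbered 51 to 840 and 595 to 2972 over 20 alternatives. Shared calls were not counted with a minimum size of change, or without a control and an almonertinib library together. With an estimated correlation 7 lists passed for siEGFR and 5 for siNC.

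Whether more calls were higher or lower also depended on the setting. After median-ratio scaling the share of higher calls passed 50% for almonertinib (40.2% to 50.4%), EGF (44.7% to 57.7%), drug minus siRNA (43.5% to 56.3%) and EGF minus siRNA (44.4% to 60.4%). With a mean of at least 5 FPKM it was 56.5% for EGF and 55.1% for EGF minus siRNA, and with a change of at least 1 it was 51.9%, 51.9% and 50.4% for EGF, drug minus siRNA and EGF minus siRNA. For siEGFR (41.5%) it was 53% with 1 weight per group and 52.5% with only the groups compared. Without a filter it was 49.6% for siNC (52.1%) and 53.8% for almonertinib against EGF (47.9%), and these were 49.6% without control 2 and 50.7% without almonertinib 2.

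Leaving out 1 library in turn, decreases with almonertinib ran from 1623 to 3634, siEGFR increases from 152 to 180 and decreases from 287 to 349, and decreases in drug minus siRNA from 731 to 1819. At these depths 1 read in a gene of 1 kb equals 0.0286 to 0.0555 FPKM, and calls were not compared across depths for genes near 1 FPKM. The simulated fits of 15 libraries recovered 61.2% of 1.5-fold changes for almonertinib and 64.2% for siEGFR, and those of 6 libraries 9% and 83.6%.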

Other observations

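The test of growth factor signalling in the siNC cultures was chosen only after its result was seen, and so were the settings that remove GC content and length trends or keep only siNC 1 and 2. The comparison with no control library in common, the axis of protein-coding genes and the splits of the siRNA arm alone were also chosen after.

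Beyond cell cycle and ERK genes, siNC cells differed from control cells in biosynthesis, stress and lineage genes (limma adjusted p, 3 libraries per group). In ribosome biogenesis 23 of 24 genes rose and 1 fell (adjusted p = 1.11e-08), with RRS1 from 11.1 ± 1.3 FPKM in control to 71.0 ± 3.16 FPKM in siNC. Of 22 ATF4 targets 16 rose and 4 fell (adjusted p = 0.00139), led by the serine synthesis enzyme PSAT1 at 1.95. Of 21 glycolysis genes 18 rose (adjusted p = 3.98e-05, and adjusted p = 0.158 with an estimated correlation), and 10 of 14 TGF-beta targets rose and 4 fell (adjusted p = 0.00706, and adjusted p = 0.113 with an estimated correlation), with ID1 at 1.94. The alveolar genes SFTPA1 and NKX2-1 were at 2.71 and 1.53 in a list with 8 of 13 higher and 2 lower (adjusted p = 0.0128, and adjusted p = 0.158 with an estimated correlation). Of 24 FOXO targets 20 fell and 2 rose (adjusted p = 1.4e-05, and adjusted p = 0.0598 with an estimated correlation), and of 25 lysosome genes 17 fell and 3 rose (adjusted p = 0.000794).

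The BCL2 family list passed in no comparison against a control. Of its 12 tested genes 2 rose and 7 fell with almonertinib (adjusted p = 0.28), 7 rose and 2 fell with EGF (adjusted p = 0.19), and 1 rose and 1 fell with siEGFR (adjusted p = 0.221). In the fits of the compared groups alone 1 rose and 1 fell with almonertinib, 4 rose and 2 fell with EGF, and 1 rose and 3 fell with siEGFR. Pro-apoptotic and anti-apoptotic members moved both alike and apart. With almonertinib the anti-apoptotic BCL2L1, MCL1 and BCL2L2 fell by 0.46, 0.38 and 0.17, as did the pro-apoptotic PMAIP1, BOK, BAK1 and BID by 0.45, 0.33, 0.31 and 0.31, while BBC3 and BAX rose by 0.53 and 0.31. With EGF BCL2L1, PMAIP1, BAK1, MCL1, BAX, BID and BCL2L2 rose by 1.13, 0.82, 0.68, 0.63, 0.27, 0.19 and 0.17, and the pro-apoptotic BMF and BCL2L11 (BIM) fell by 1.97 and 0.44. BCL2L11 was at -0.08 with almonertinib (adjusted p = 0.44).

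The siNC libraries differed from the control libraries at 9899 genes. The tables argue against depth as the whole cause, with 8968 genes past the threshold when only siNC 1 and 2, close in depth to control, were used. They also argue against GC content or gene length bias, since 10166 genes passed after these trends were removed, 8388 of them shared with the 9899. Growth factor signalling that was higher in the siNC cultures stays open as a hypothesis. The covariance of the EGF and siNC effects lay 0.22 above the mean of 100 simulations of shared controls with independent genes. The highest of these and of 100 more in which genes varied together gave 0.0646. Of 6165 genes called in both, 91.6% went the same way. With 1 control library for one effect and the other 2 for the other, the effects correlated with r = 0.5118 to 0.6743 over the 6 ways. Other lists went against EGF: of 23 cholesterol synthesis genes, 20 of which rose with EGF, 10 fell and 2 rose in siNC (adjusted p = 0.0326, and adjusted p = 0.101 with an estimated correlation). Of 17 immediate early genes 9 rose and 7 fell (adjusted p = 0.51), with EGR1 from 13.7 ± 1.24 to 4.5 ± 0.249 FPKM. The hypothesis cannot be told apart from other culture differences, because the ERK list loses its call (adjusted p = 0.0863 with an estimated correlation), and transfection, medium and density are not given in the sources used here.

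Replicates of control, almonertinib and EGF differed along 1 shared axis that held 45.7% of the variance within groups, with scores of 0.20 for control 1 and 0.17 for almonertinib 3 against -0.16 for control 2, -0.14 for EGF 2 and -0.13 for almonertinib 2. Depth is argued against, since library total and score correlated with r = 0.23 over 15 libraries centred within groups. GC content or length bias stays open: these explained 47.8% of the axis over genes, with median loadings of 1.34 for the 10% of genes poorest in GC and -0.71 for the 10% richest. Unspliced, nuclear or genomic sequence also stays open, since the share of reads on long noncoding RNA genes correlated with the score with r = 0.93 (exact permutation within groups, two-sided p = 0.00463, the smallest that 216 permutations can give) and rho = 0.93 (permutation p = 0.0185) over 9 libraries, and r = 0.91 without the 2 farthest. With the axis computed from protein-coding genes alone r was 0.9323, but as genes the 1293 long noncoding RNAs had a median loading of 0.316, close to the 0.24 of protein-coding genes. No biological explanation was tested.

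The 10 splits of 6 libraries are too few for a share under 0.05. The real split was the only 1 of 10 with as many genes for almonertinib (4517, highest other 3177), EGF (7396 and 485), siEGFR (819 and 1), siNC (9899 and 0) and almonertinib against EGF (9393 and 0). The almonertinib split with 3177 genes exchanged control 2 and almonertinib 3, and the EGF split with 485 set control 1, EGF 1 and EGF 3 against the rest, which points to the sample structure along the axis above. For the differences, 100 of the 200 splits within both arms were drawn, and the real one alone gave as many genes: 2049 for drug minus siRNA (highest other drawn 1482, with control 2 and almonertinib 3 exchanged) and 5752 for EGF minus siRNA (5486). With the almonertinib arm intact, 2 of the 20 labelings of the siRNA arm gave as many genes, and exchanging siNC and siEGFR, which turns the difference into a sum, gave 3218, with 715 as the lowest. With the EGF arm intact 1 of 20 did, and the others gave 4327 to 5486, that exchange being the highest. The counts thus rest mainly on the drug or EGF arm, and 20 labelings are too few for a share under 0.05.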
